A study of Pinus pinaster with 21 samples.

How the data were processed

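Small RNA was sequenced from the roots of maritime pine (Pinus pinaster), a conifer, in a test of the root's response to ammonium supplied as NH4Cl. Per the labels' protocols, 1-month-old seedlings spent 3 days on a nutrient solution without nitrogen and then received 80 mL of water, of 0.1 mM NH4Cl or of 3 mM NH4Cl. Roots were taken before this irrigation (0 h) and 2 h and 24 h after it, 10 seedlings were pooled for each sample, and the whole experiment was done 3 times. Molecules of 18 to 30 bp were selected on polyacrylamide gels, libraries were made with a TruSeq small RNA kit and single-end reads of 50 bp were produced, again per the labels' protocols. The 21 libraries form 7 groups of 3, taken from the labels' treatment and time fields, and the replicate number of each library is the number of its experiment.

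The authors deposited a table of whole-number read counts, not normalised, for 32711 identifiers in the 21 libraries. Per the submitters' processing notes, bcl2fastq and edgeR were used, with no versions named. The aligner, the miRNA caller, the genome build and any filter on the identifiers are not given in the sources used here. The identifiers are serial labels from MIR_0 upwards that the table pairs with no name, sequence or position, and no genome was used here. For this reason the miRNA families and family lists that had been fixed before the data were examined (nitrogen, phosphate and sulfate, copper, auxin and lateral root, phase change, small RNA machinery, NBS-LRR, Pinaceae and other-source lists) matched 0 identifiers. Their tests, their shares of each library and the sums over families or identical sequences were not run. What an identifier is known to do cannot be stated for the same reason.

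The deposited counts have a property that shapes every test. No count between 0 and 5 occurs, the identifiers are numbered in the order in which the libraries first list them, and 86.6% of all cells are 0. Of the 193 identifiers that at least 2 of the 17 libraries described next list, with a median listed count of at least 10000, 131 stood at 0 in at least 1 of these libraries. Among the 1989 identifiers that at least 10 of these 17 libraries list, 97.2% of the listed values lay within 1 log2 unit of that identifier's own median. Other identifiers were not part of this check. Listing rose with the count, from 18.4% of the 17 libraries for identifiers with a median listed count of 5 to under 20 to 64.8% for those of at least 10000 (identifiers listed by at least 2). A 0 is therefore read here as "not listed in this library", no detection floor is computed from it and no fold is given against it. A library was called full when it listed at least 50% of the identifiers that at least 10 of the other libraries list. This rule was set after the table was seen. It held for 17 libraries and not for the other 4. The 17 full libraries all list the same 416 identifiers, called shared identifiers below, which carry 51.5% to 62.3% of the counts of these libraries.

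The main test, fixed before the data were examined, was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, the filterByExpr filter (minimum count 10, minimum total count 15) and all 21 libraries in a single fit without a block. It covered 8537 identifiers, was two-sided, and counted identifiers with a Benjamini-Hochberg adjusted p under 0.05. It was run for 9 pairs of groups, for 2 interactions of ammonium with time and for any difference among the 7 groups. Alternatives fixed with it were RLE factors, library totals, upper-quartile factors, no filter, a mean CPM of at least 10, DESeq2 1.42.0, limma-voom (limma 3.58.1), the experiment as a replicate block, only the groups compared, each library left out and each experiment left out. Alternatives chosen after the data were seen were the omission of the 4 libraries, the restriction to the shared identifiers of the 17 full libraries with and without the block, unlisted values treated as missing in limma, DESeq2 with poscounts size factors, and contrasts that pool all ammonium groups or all groups of a time. On the shared identifiers, CPM is scaled to the shared counts of each library with TMM factors, and log2 fold changes, standard errors and 95% intervals come from limma on log2 CPM.

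The rule for named identifiers, fixed before the data were examined, took those past the threshold with non-overlapping groups and a mean CPM of at least 5. Where fewer than 5 passed, it took the 5 with the smallest unadjusted p, whose values are given without calling them changes. It also took the 10 identifiers with the highest mean CPM. All other identifiers named were chosen after their values were seen.

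The labels say that a replicate number marks a separate run of the experiment, so equal numbers share a batch. On the shared identifiers, deviations from the group means correlated on average at 0.254 between libraries of the same experiment (35 pairs) and at -0.123 between libraries of different experiments (71 pairs). Deviations within a group cancel out, so the negative average largely follows from the positive one and is no separate observation. The same-experiment correlations ranged from -0.201 to 0.578. As a check only for a library deposited under 2 names, the chi-square per degree of freedom of replicate pairs ran from 76.6 to 1353, where a copy or a second sequencing of it would give about 1 or less.

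The scripts were tested on simulated counts for 3 mM ammonium against water at 2 h, with real means and totals, a biological coefficient of variation of 0.25 and 200 changed identifiers among 8537. Means were taken over listed values, and the changed identifiers were drawn from those that every library of both groups lists. The shares recovered hold for such identifiers only. With every identifier listed in every library, edgeR recovered 44% of those changed by 1 log2 unit, 92% at 1.5, 98% at 2 and 100% at 3. When the zeros of the deposited table were imposed on the same kind of data, edgeR recovered 0% at each of the 4 sizes, the fitted coefficient of variation rose to 3.12, and DESeq2 also recovered 0% while calling 876 unchanged identifiers (19 with every identifier listed). With 40 changed identifiers among the 416 shared ones, edgeR recovered 80% of those changed by 1 log2 unit and 100% at 1.5, 2 and 3. Each of these shares rests on 10 identifiers, and all were simulated with the same coefficient of variation. In the real data an estimate of 2.46 log2 units did not pass in this comparison. The simulated shares therefore need not hold for the real test.

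Library totals ran from 1180505 to 9603954 counts. PCR reads without molecular identifiers are not independent molecules, so the precision of the comparisons was judged from the spread between experiments and not from the counts.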

Results

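The roots of maritime pine seedlings were profiled for small RNA before irrigation and 2 h and 24 h after irrigation with water, 0.1 mM ammonium or 3 mM ammonium, with 3 libraries from 3 independent experiments in each of the 7 groups. The study asks how the small RNA population of the root responds to ammonium supply over time. Each library listed between 3872 and 5408 identifiers, each identifier standing for a small RNA. Of the 32711 identifiers, 19469 (59.5%) were listed by 1 library only and 2 were listed by all 21.

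**Figure D1:**
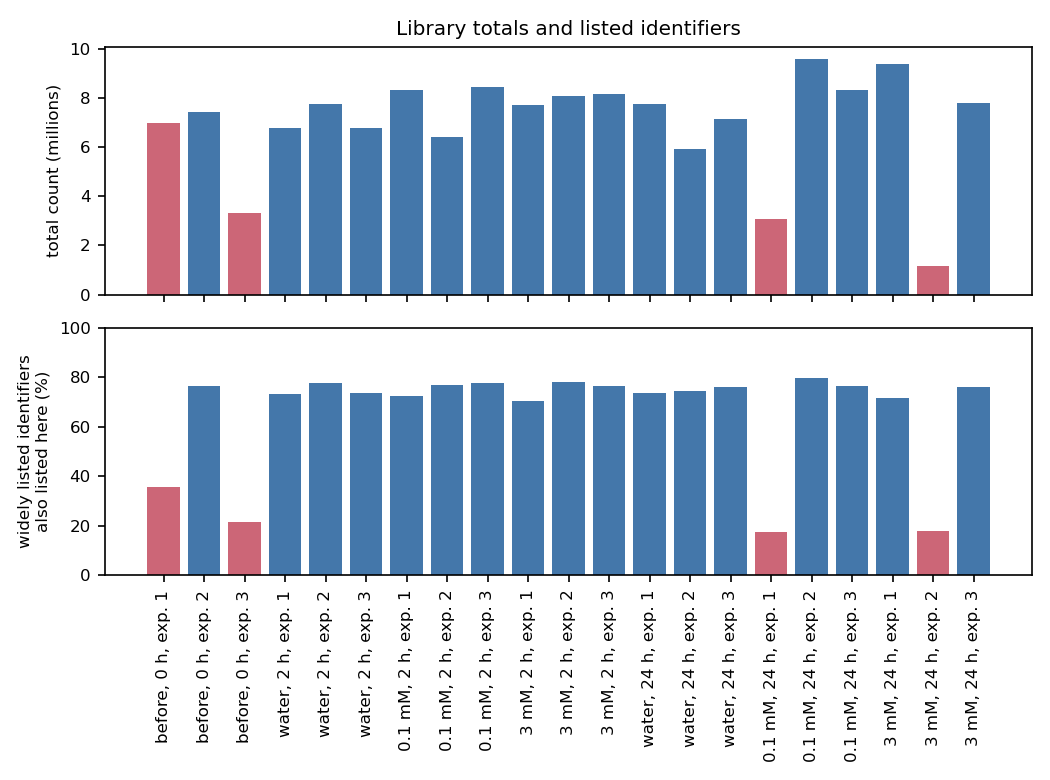
Total count (top, axis in units of 1e6) and the share in percent of widely listed identifiers that each library also lists (bottom), 1 bar for each of the 21 libraries, exp. standing for experiment. The 17 libraries in blue list 70.4% to 79.7% of these identifiers, and the 4 in red list 17.4% to 35.5%.

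Library totals ranged from 5947601 to 9603954 counts in 17 libraries. The other 4, namely before irrigation replicates 1 and 3, 0.1 mM at 24 h replicate 1 and 3 mM at 24 h replicate 2, had totals of 6982894, 3332237, 3086103 and 1180505. They listed 35.5%, 21.4%, 17.4% and 18.0% of the identifiers listed by at least 10 other libraries. All 9 libraries at 2 h were full. At 24 h, 3 water libraries and 2 of each ammonium dose were full, and before irrigation only replicate 2 was.

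In the 17 full libraries, a few small RNAs held much of the shared counts in every condition. The shared counts are 51.5% to 62.3% of the counts of a full library. MIR_828 and MIR_352 were each listed by 19 of the 21 libraries, and no count in 3 mM at 24 h replicate 2 exceeded 49264. MIR_828 was the most abundant identifier, with 227700 CPM of the shared counts before irrigation (1 library), 231000 ± 17500 (SD, n = 3) after water, 227400 ± 19000 (SD, n = 3) after 0.1 mM and 227100 ± 15200 (SD, n = 3) after 3 mM ammonium at 2 h. MIR_352 followed with 128400 ± 15900 (SD, n = 3) after water, 123200 ± 8170 (SD, n = 3) after 0.1 mM and 127400 ± 5350 (SD, n = 3) after 3 mM ammonium at 2 h. At 24 h, MIR_828 stood at 200600 ± 7060 (SD, n = 3) after water, at 213000 ± 12800 (SD, n = 2) after 0.1 mM and at 207600 ± 36100 (SD, n = 2) after 3 mM ammonium. The share of MIR_828 in the shared counts, which unlike CPM carries no TMM scaling, differed between 3 mM ammonium and water by -0.799 percentage points at 2 h (exact permutation p = 0.7, two-sided) and by -2.42 points at 24 h (exact permutation p = 0.2, two-sided). At 24 h the direction thus turned with the scaling, from a share of 18.52% against 20.94% to a CPM above that of water. At 0.1 mM the share differed from water by -0.0631 points at 2 h (exact permutation p = 1, two-sided) and by 1.72 points at 24 h (exact permutation p = 0.4, two-sided). The smallest p these designs allow is 0.1, so none of these tests could pass 0.05. Between 3 mM and 0.1 mM at 24 h the share differed by -4.14 points (exact permutation p = 0.333, two-sided, the smallest that 2 libraries against 2 allow). The libraries at 3 mM came from experiments 1 and 3 and those at 0.1 mM from experiments 2 and 3. This difference thus partly mixes dose with experiment. Within experiment 3 the share was 18.65% at 3 mM and 22.66% at 0.1 mM. Of the 10 most abundant identifiers, 9 were shared identifiers.

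At 3 mM, no shared small RNA passed the test against water at 2 h. The shared set holds only identifiers that all 17 full libraries list. A small RNA that ammonium switched fully on or off could not be in it, here or in the comparisons below. Among the 416 shared identifiers, 212 were higher and 204 lower after ammonium, the median absolute difference was 0.15 log2 units, and the 95% interval of the difference lay within 1 log2 unit of 0 for 358 of them. In 2 of the 416 the estimate itself was larger than 1 log2 unit (largest 2.46), and neither passed the test. MIR_828 differed by -0.02 log2 units (SE 0.17, interval -0.38 to 0.33) and MIR_352 by 0.00 (SE 0.15, interval -0.34 to 0.33). Of the other abundant shared identifiers, MIR_353 was at -0.28 (interval -0.67 to 0.10). The intervals of the rest reached past 1 log2 unit. MIR_30 was at 0.80 (-0.41 to 2.01), MIR_57 at 0.32 (-0.73 to 1.37) and MIR_183 at 0.29 (-0.77 to 1.35). MIR_62 was at 0.23 (-0.58 to 1.03), MIR_6 at -0.07 (-1.08 to 0.95) and MIR_86 at -0.29 (-1.36 to 0.77). The smallest p values belonged to MIR_5125, at 0.49 log2 units above water (SE 0.11), and MIR_1092, at -0.51 (SE 0.13), both with an adjusted p of 0.342 in edgeR. The edgeR test called 0 of the 416, with 18 at an unadjusted p under 0.05 where 21 are expected by chance, and limma called 0. With the experiment as a block it also called 0, but 39 stood at an unadjusted p under 0.05 (smallest adjusted p 0.311).

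Over all 8537 identifiers tested, the main edgeR test also called 0 for 3 mM ammonium against water at 2 h. It gave 429 identifiers at an unadjusted p under 0.05, where 427 are expected by chance. DESeq2 called 827 and limma-voom called 0. The identifiers with the smallest p differed in whether they were listed. MIR_15 had 69339 and 3970 counts in 2 of the ammonium libraries and was at 0 in the third and in the 3 water libraries, and MIR_12247 had 51178 counts in 1 water library and was at 0 in the other 5 (adjusted p = 0.39 for both, edgeR). In all, 53 identifiers were listed by the 3 ammonium libraries and no water library and 50 the other way round, a sum of 103, and other splits of the same 6 libraries gave 99 to 137. For 0.1 mM at 2 h the sum was 108 (other splits 103 to 141).

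At 0.1 mM, no shared small RNA passed the test against water at 2 h. In the shared set, 215 identifiers were higher and 201 lower, the median absolute difference was 0.11 log2 units, and 367 of the 416 intervals lay within 1 log2 unit of 0. The smallest p values belonged to MIR_4894, 0.58 log2 units above water (SE 0.17), and MIR_1205, 1.29 above it (SE 0.48), with an adjusted p of 0.999 in edgeR. MIR_86, the ninth most abundant identifier, stood at 12370 ± 4950 CPM (SD, n = 3) after ammonium and at 23700 ± 15600 CPM (SD, n = 3) after water. It was lower after ammonium in 3 of 3 experiments (18020 against 41750 CPM in experiment 1, 10280 against 15080 in experiment 2 and 8808 against 14280 in experiment 3). With the experiment as a block, its difference was -0.82 log2 units (SE 0.21, interval -1.27 to -0.37) and had the smallest p of the 416, with an adjusted p of 0.952 in edgeR. At 24 h it went the other way in both experiments that can be compared (10680 against 9475 CPM in experiment 2 and 13190 against 10530 in experiment 3), with a blocked difference of 0.09 log2 units (SE 0.24, interval -0.43 to 0.61). At 3 mM and 2 h it was lower than after water in experiments 1 and 2 and higher in experiment 3 (15520 against 14280 CPM). The edgeR test called 0 shared identifiers (9 at an unadjusted p under 0.05, and 18 with the block) and 0 of all 8537 (449 at an unadjusted p under 0.05), while DESeq2 called 816 and limma-voom 3 of the latter. Of the identifiers with the smallest p, MIR_14 had 32170 and 56583 counts in 2 ammonium libraries and 0 in the third and in the 3 water libraries, and MIR_12234 had 33210 and 33186 counts in 2 water libraries and 0 in the third and in the 3 ammonium libraries (adjusted p = 0.397 for both, edgeR).

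**Figure D2:**
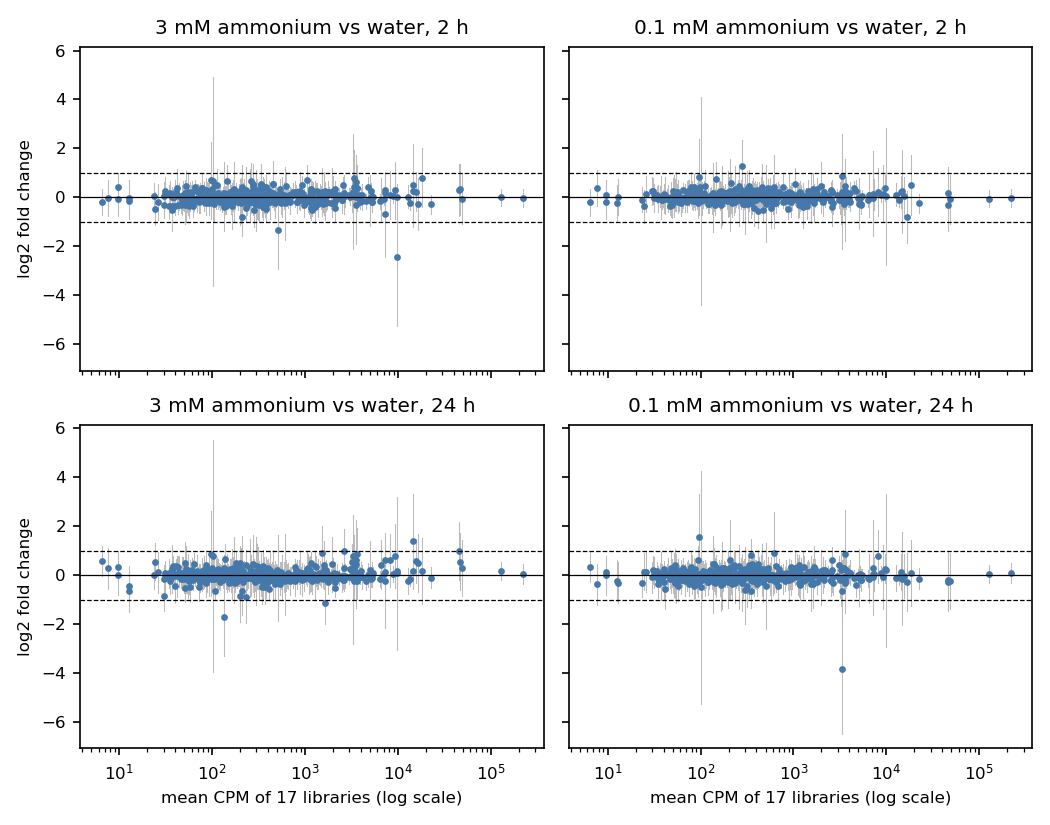
Log2 fold change against water (vertical) and mean CPM of 17 libraries (horizontal, log scale) of the 416 shared identifiers, for both ammonium doses at 2 h and 24 h, with 95% limma intervals as grey lines and dashed lines at 1 log2 unit either way. Between 347 and 367 of the 416 intervals lie within the dashed lines in each panel.

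After 24 h no shared small RNA passed the test against water at either dose. At 3 mM (2 full libraries against 3), 212 were higher and 204 lower, the median absolute difference was 0.13 log2 units and 347 of the 416 intervals lay within 1 log2 unit of 0. In 3 the estimate itself was larger than 1 log2 unit (largest 1.72). The abundant MIR_183 was at 0.99 log2 units (SE 0.55, interval -0.19 to 2.18). It stood at 105100 ± 98600 CPM (SD, n = 2) after 3 mM ammonium and at 42120 ± 19600 CPM (SD, n = 3) after water. MIR_1388 was at -0.65 log2 units (SE 0.18) and MIR_4748 at -0.52 (SE 0.17), both with an adjusted p of 0.997 in edgeR. At 0.1 mM (2 against 3), 350 intervals lay within 1 log2 unit of 0 and 2 estimates were larger than 1 log2 unit (largest 3.86). MIR_1092 was at -0.42 log2 units (SE 0.15) and MIR_1162 at 0.47 (SE 0.18), again with an adjusted p of 0.997. The edgeR test called 0 shared identifiers at either dose, with 15 and 7 at an unadjusted p under 0.05 (25 and 12 with the block). Experiment 2 has no full library at 3 mM and 24 h, and experiment 1 has none at 0.1 mM and 24 h. The differences without the block thus partly mix dose with experiment. With the block, 372 intervals at 3 mM and 380 at 0.1 mM lay within 1 log2 unit of 0.

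Over all 8537 identifiers, edgeR called 0 at 24 h for 3 mM and 0 for 0.1 mM ammonium against water, with 491 and 493 at an unadjusted p under 0.05. DESeq2 called 965 and 907, and limma-voom 0 and 0. MIR_217 was listed by 16 of the 21 libraries and had 44363, 22946 and 26962 counts in the water libraries at 24 h but was at 0 in all 3 libraries at 3 mM, while MIR_767 had 51435, 24589 and 14461 counts at 3 mM and was at 0 in all 3 water libraries (adjusted p = 0.369 for both, edgeR). MIR_53, also listed by 16 libraries, had 20044, 18214 and 16130 counts after water at 24 h and was at 0 in all 3 libraries at 0.1 mM (adjusted p = 0.376, edgeR). Such all-or-none listing was no more frequent than in most other splits of the same 6 libraries. At 3 mM, 14 identifiers were listed by the 3 ammonium libraries only and 62 by the 3 water libraries only, a sum of 76 (other splits 96 to 150), and at 0.1 mM 47 and 62, a sum of 109 (other splits 103 to 149). In both, 1 ammonium library lists few of the identifiers that at least 10 other libraries list. Without the 4 libraries that list few shared identifiers, MIR_53 passed the threshold for 0.1 mM against water at 24 h (adjusted p = 0.000189, edgeR), listed by all 15 other full libraries and by neither of the 2 at 0.1 mM. By the same difference in listing, MIR_53 then also passed for 3 mM against 0.1 mM (adjusted p = 0.000227) and in the interaction of 0.1 mM with time (adjusted p = 0.000284).

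The higher dose was then set against the lower. At 2 h, MIR_5125 was 0.49 log2 units higher at 3 mM than at 0.1 mM (SE 0.11, adjusted p = 0.392 in edgeR) and MIR_4574 was at -0.53 (SE 0.15, adjusted p = 0.854). At 24 h (2 libraries against 2), MIR_1388 was at -0.75 (SE 0.19) and MIR_844 at -1.50 (SE 0.44), both with an adjusted p of 0.719. Of the 416 intervals, 365 at 2 h and 336 at 24 h lay within 1 log2 unit of 0, and 2 and 9 estimates were larger than 1 log2 unit (largest 2.49 and 3.68). At 24 h the full libraries at 3 mM came from experiments 1 and 3 and those at 0.1 mM from experiments 2 and 3. The differences at 24 h without the block thus partly mix dose with experiment. With the experiment as a block, 362 intervals at 24 h lay within 1 log2 unit of 0 and 4 estimates were larger than 1 log2 unit (largest 3.85). MIR_1388 was then at -0.82 (SE 0.20) and MIR_844 at -1.64 (SE 0.44). The edgeR test called 0 shared identifiers at both times (14 and 10 at an unadjusted p under 0.05, and 19 and 12 with the block). Of all 8537 it called 0 at 2 h and 0 at 24 h, with 424 and 533 at an unadjusted p under 0.05, while DESeq2 called 822 and 981 and limma-voom 4 and 0. MIR_4133 had 58515 and 36810 counts in 2 libraries at 0.1 mM and 2 h and was at 0 in all 3 at 3 mM, and MIR_346 had 102256 and 49630 counts in 2 libraries at 3 mM and 24 h and was at 0 in all 3 at 0.1 mM. Identifiers listed by all 3 libraries of one dose and none of the other numbered 107 at 2 h (other splits 87 to 147) and 54 at 24 h (other splits 57 to 273).

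With all ammonium groups pooled against water after irrigation (10 full libraries against 6), the intervals narrowed and 399 of the 416 lay within 1 log2 unit of 0. The identifier with the smallest p, MIR_1092, was at -0.36 log2 units (SE 0.08, interval -0.54 to -0.18, adjusted p = 0.262 in edgeR), and MIR_4830 was at 0.43 (SE 0.13, adjusted p = 0.894). The edgeR test called 0 shared identifiers in this contrast, chosen after the data were seen, with 17 at an unadjusted p under 0.05 (27 with the block). Leaving out 0.1 mM at 24 h replicate 2, or 3 mM at 24 h replicate 3, left 1 full library in that group. Such a library has no spread of its own, so no call is taken from these refits. MIR_839 was at -1.69 log2 units in the first and MIR_743 at -0.93 in the second (edgeR). The same refits put them at -2.42 and -1.2 in the contrast of 24 h with 2 h.

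Sampling time was compared in the water groups and then over all treatments. Between 24 h and 2 h after water, MIR_1176 was 0.49 log2 units higher (SE 0.13) and MIR_4894 0.61 higher (SE 0.17), both with an adjusted p of 0.509, and edgeR called 0 of 416 shared identifiers (18 at an unadjusted p under 0.05, and 32 with the block) and 0 of 8537 (453 at an unadjusted p under 0.05), with 854 calls by DESeq2 and 0 by limma-voom. With the treatments pooled (7 full libraries at 24 h against 9 at 2 h, a contrast chosen after the data were seen), MIR_1792 rose from 30.6 ± 3.05 CPM (SD, n = 9) to 48.3 ± 7.67 CPM (SD, n = 7), by 0.67 log2 units (SE 0.10, interval 0.46 to 0.88, adjusted p = 0.00329 in edgeR). Its lowest value at 24 h, 35.9 CPM, lay above its highest value at 2 h, 33.8 CPM. Before irrigation it stood at 36.9 CPM in the single full library. MIR_1792 passed in all 16 refits that leave out 1 library, with adjusted p from 0.000947 to 0.0233. MIR_1870 stood at 53.2 ± 8.90 CPM (SD, n = 9) at 2 h and 78.2 ± 8.68 CPM (SD, n = 7) at 24 h, 0.56 log2 units apart (SE 0.12), with an adjusted p of 0.0902, which became 0.0249 with the experiment as a block. Without the block, MIR_1870 passed in only 2 of the 16 refits that leave out 1 library, with edgeR adjusted p from 0.0405 to 0.253. Chance was not excluded for the count without the block, since 19 of 100 assignments of the times to the libraries gave at least 1 call. Nor was it with the block, where 12 of 100 assignments within experiments gave at least 2. The assignments could leave 1 library in a group, where the real groups after irrigation hold 2 or 3 full libraries. They also concern the number of calls and not MIR_1792 or MIR_1870 itself.

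**Figure D3:**
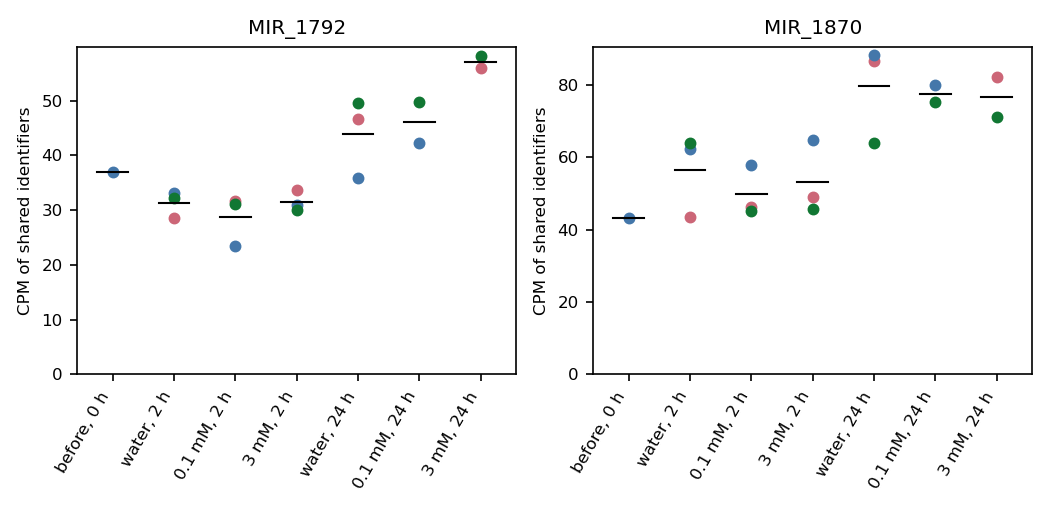
CPM of MIR_1792 (left) and MIR_1870 (right) in the 17 full libraries by group, 1 point for each library coloured by experiment (red 1, blue 2, green 3), with the group mean as a line. MIR_1792 lies at 23.6 to 33.8 CPM in the 9 libraries at 2 h and at 35.9 to 58.1 CPM in the 7 at 24 h.

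Irrigation with water was compared with the roots before irrigation, where 1 of the 3 libraries was full. These tests set 1 library against 3 and assume that it varies as the libraries of the other groups do, since a single library has no spread of its own. MIR_1375 passed in the shared set, 1.93 log2 units apart at 2 h (SE 0.25, adjusted p = 0.00501 in edgeR) and 1.51 at 24 h (SE 0.25, adjusted p = 0.0416), with 25.8 CPM in that library against 98.8 ± 9.54 CPM (SD, n = 3) and 74.5 ± 12.9 CPM (SD, n = 3). It had 114 counts there, or 15.4 CPM of the whole library. Before irrigation replicate 1, which is not full, had 421 counts or 60.3 CPM, within the 53.6 to 62.5 CPM of the water libraries at 2 h, and replicate 3 did not list it, so no change of MIR_1375 with irrigation is claimed. MIR_86, at 3389 CPM before and 23700 ± 15600 CPM (SD, n = 3) at 2 h, passed with the experiment as a block (adjusted p = 0.0116) and not without it (adjusted p = 0.877). This too rests on replicate 2 before irrigation, with 14960 counts of MIR_86 or 2020 CPM of the whole library. Replicates 1 and 3 had 13000 and 20700 CPM, within the 8090 to 25300 CPM of the water libraries at 2 h, so no change of MIR_86 is claimed either. Over all 8537 identifiers, edgeR called 0 at 2 h and 0 at 24 h, with 550 and 580 at an unadjusted p under 0.05. DESeq2 called 1083 and 1112 and limma-voom 0 and 0, and the block gave 2 calls at 24 h, MIR_832 and MIR_12279.

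The effect of ammonium was compared between 24 h and 2 h as an interaction. Among shared identifiers, MIR_4748 was at -0.84 log2 units for 3 mM (SE 0.23) and MIR_5084 at -0.59 for 0.1 mM (SE 0.18), with adjusted p of 0.998 and 0.995, and edgeR called 0 in both interactions (14 and 7 at an unadjusted p under 0.05, and 24 and 11 with the block). Over all 8537 identifiers, edgeR called 0 for 3 mM and 0 for 0.1 mM, with 1022 and 1009 at an unadjusted p under 0.05. DESeq2 called 1240 and 1168, and limma-voom 2 and 5. With the experiment as a block, MIR_15 and MIR_12247 passed for 3 mM, and a fit of only the 4 groups compared gave 32 calls. Without 0.1 mM at 24 h replicate 1, MIR_7281, MIR_15482 and MIR_20027 passed for 0.1 mM (adjusted p = 0.0443 for each), and without 3 mM at 24 h replicate 2, MIR_4133 passed for 3 mM. MIR_15, MIR_12247 and MIR_4133 were listed by 5, 3 and 4 of the 21 libraries.

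Any difference among the 7 groups was called by edgeR for 130 of 8537 identifiers. This count was 9 with the experiment as a block, 0 without experiment 1 or experiment 3, 4 without experiment 2, and 1 without the 4 libraries that list few shared identifiers. No shared identifier was called by edgeR (18 of 416 at an unadjusted p under 0.05). Over all 8537, DESeq2's likelihood ratio test called 0 (6 at an unadjusted p under 0.05) and limma-voom 19.

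On the shared identifiers, 99 of 416 differed between experiment 1 (5 full libraries) and the mean of experiments 2 and 3 (12 full libraries) with the groups kept in the model, 55 higher and 44 lower in experiment 1, with a median size of 0.48 log2 units (edgeR, adjusted p under 0.05). MIR_94 stood at 29940 ± 10700 CPM (SD, n = 5) in experiment 1 and at 8211 ± 2710 CPM (SD, n = 12) in the others, 1.85 log2 units higher with an adjusted p of 1.01e-05. MIR_74 stood at 532.7 ± 58.0 CPM (SD, n = 5) against 201.4 ± 27.3 CPM (SD, n = 12), 1.38 log2 units higher with an adjusted p of 3.68e-06. Experiments 2 and 3 differed in 0 identifiers. With 3 experiments, these tests measure the spread between libraries and not the spread between experiments. The first principal component of the shared identifiers, with 27.2% of the variance, separated the libraries of experiment 1 from all others.

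**Figure D4:**
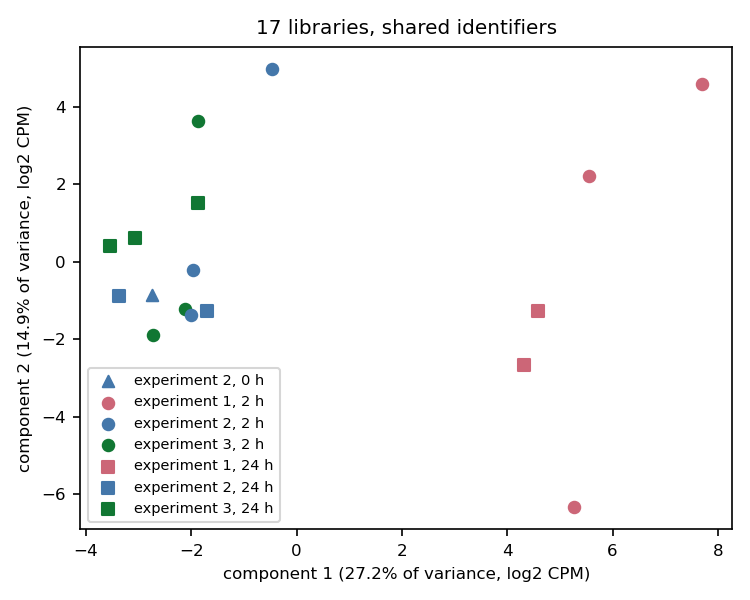
First and second principal components of log2 CPM of the 416 shared identifiers in the 17 full libraries, coloured by experiment, with triangles, circles and squares for 0, 2 and 24 h. The 5 libraries of experiment 1 lie to the right of the 12 others along the first component, which holds 27.2% of the variance.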

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

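Chosen after the data were seen were the omission of the 4 libraries that list few shared identifiers, the shared-identifier tests and their block, unlisted values as missing, poscounts size factors and both pooled contrasts. Of 324 alternative counts, 252 lay within 1.5 times the main count and 72 did not. The cause of each move was not tested unless stated. Depth limits what can be said of identifiers with low counts, which fewer libraries list. In simulated 3 mM against water data at 2 h, imposing these zeros took the share recovered at 3 log2 units from 100% to 0%, so a count of 0 over all 8537 identifiers says nothing about stability.

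The 9 group comparisons and 2 interactions each gave 0 calls in edgeR, with 424 to 1022 identifiers at an unadjusted p under 0.05. RLE factors (which rest on 2 identifiers), library totals, no filter, a mean CPM of at least 10 and each experiment left out also gave 0 for all 11. Upper-quartile factors gave no value, since that quartile is 0 in 4 libraries. Tests of families and lists, and sums over identical sequences, could not be run because 0 identifiers could be matched to a name.

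With DESeq2 the calls were 827 for 3 mM against water and 816 for 0.1 mM against water at 2 h, 965 and 907 at 24 h, 822 for 3 mM against 0.1 mM at 2 h and 981 at 24 h. They were 1083 for water at 2 h against before irrigation, 1112 for water at 24 h against before, 854 for water at 24 h against 2 h, and 1240 and 1168 for the interactions of 3 mM and 0.1 mM with time. Poscounts size factors gave, in the same order, 779, 758, 908, 858, 791, 930, 1008, 1049, 796, 1168 and 1105. In the simulation DESeq2 called 19 unchanged identifiers with every identifier listed and 876 with the deposited zeros. Limma-voom gave 3 calls for 0.1 mM against water at 2 h (MIR_4928, MIR_7601 and MIR_14125), 4 for 3 mM against 0.1 mM at 2 h (MIR_4804, MIR_4928, MIR_7583 and MIR_7601), and 2 and 5 for the interactions of 3 mM and 0.1 mM.

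The replicate block gave 2 calls for water at 24 h against before irrigation, 2 for the interaction of 3 mM with time and 9 for any difference among the 7 groups. It changed no other count over all identifiers. Only the groups compared gave 32 calls for the interaction of 3 mM. With each library left out, the interactions ranged from 0 to 1 call for 3 mM (1 without 3 mM at 24 h replicate 2) and from 0 to 3 for 0.1 mM (3 without 0.1 mM at 24 h replicate 1). Without the 4 libraries there was 1 call for 0.1 mM against water at 24 h, 1 for 3 mM against 0.1 mM at 24 h and 1 for the interaction of 0.1 mM, all of them MIR_53. The same omission gave 2 calls for water against before irrigation at 2 h and 2 at 24 h, MIR_4801 and MIR_4829 both times. Shared identifiers gave 1 call for water at 2 h and 1 at 24 h against before irrigation, and 2 and 1 with the block. Unlisted values as missing gave 1 call for 0.1 mM against water at 24 h, MIR_1073 (lower, limma adjusted p = 0.00298).

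The 130 identifiers with any difference among the groups became 197 with no filter, 466 with a mean CPM of at least 10, 0 with DESeq2 and 19 with limma-voom. They were 57 to 182 with each library left out (57 without water at 2 h replicate 2, 182 without 3 mM at 24 h replicate 2). Without experiments 1, 2 and 3 they were 0, 4 and 0, and without the 4 libraries 1. Shared identifiers gave 0, and 0 with the block. RLE factors gave 130 and library totals 169.

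The pooled contrast of ammonium with water gave 0 calls. With each library left out it also gave 0, apart from refits that leave 1 full library in an ammonium group at 24 h, from which no call is taken. That of 24 h with 2 h gave 1 call, 2 with the block and 1 to 3 with each library left out. For the identifiers named by the fixed rule, 22 refits gave no value because every remaining library stood at 0. None of these identifiers was called in the main pairs and interactions, so they had no called direction to reverse. Reversals of directions that were not called are not given here. MIR_1792, called in the pooled contrast of 24 h with 2 h, stayed higher at 24 h in all 16 refits (0.63 to 0.72 log2 units).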

Other observations

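The splits of all fixed comparisons, the regroupings for DESeq2 and the tests of library depth, of library totals, of another tissue or organism and of the times with a block were set before their results were seen. The splits of the pooled contrasts without a block and of experiment 1, and the tests of shallow sequencing, of rows left out, of a reporting minimum and of different identifiers for one small RNA, were chosen only after the result was seen, as was the comparison of sizes with and without the scaled total.

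MIR_53 was chosen for a closer description after its values were seen. Its median count was 16516 in the 15 full libraries that list it, both full libraries at 3 mM and 24 h among them, against 0 in all 3 libraries at 0.1 mM and 24 h. Of 231 identifiers missing from exactly 2 of the 17 full libraries, 22 lacked 2 libraries of the same group, where 23.8 are expected if all pairs are equally likely, and 2 lacked both full libraries at 0.1 mM and 24 h, where 1.70 are expected. The listing of MIR_53 is thus no rarer than such chance allows. In 81 the missing libraries came from the same experiment (67.9 expected).

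The first pattern is that 4 libraries list few of the shared identifiers. Shallow sequencing is argued against only for the listed identifiers that at least 10 other libraries also list. These had about their usual counts, the lowest median log2 ratio being -0.24, while the totals lie as far as -2.72 log2 units from the median full total. They number 767, 469, 383 and 396 of 4100, 4098, 4009 and 4778 listed (before irrigation replicates 1 and 3, 0.1 mM replicate 1 and 3 mM replicate 2 at 24 h). The others were not compared, and 1582 to 2769 per library are listed nowhere else. The median listed count was 21 to 37 in the 4 libraries, against 105 to 119 in the full ones. Rows left out of otherwise full libraries stays open only as part of the cause, since leaving out rows cannot add identifiers. The 4 libraries each listed 1582 to 2769 identifiers that no other library lists, against 482 to 1003 in the full ones. It needs the listed identifiers to stand at their usual counts, and at the lowest 91.7% of those shared lay within 1 log2 unit of them, against at least 95.2% in the full libraries. It would not account for the 4, 3 and 4 of the shared identifiers that before irrigation replicate 3, 0.1 mM at 24 h replicate 1 and 3 mM at 24 h replicate 2 do list at over 3 log2 units below their usual counts (at most 1 in a full library), such as MIR_57 at 140 counts in the last. Another tissue or organism in the tube stays open. The lowest correlation with the full libraries was 0.577, in 3 mM at 24 h replicate 2 over the 70 shared identifiers it lists, and the others were 0.986, 0.900 and 0.894.

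The second pattern is that abundant identifiers are listed by some libraries only. A reporting minimum is argued against for these identifiers, though not for those with low counts, since 67.9% of the identifiers with a median count of at least 10000 are missing from at least 1 of the 17 full libraries. The same small RNA under different identifiers in different libraries may account for part of it. The search covered 474 identifiers with a median count of at least 2000, a lower bound than the 10000 above. It found 43 pairs, made of 72 identifiers, with similar counts (within 0.5 log2 units). The libraries of a pair do not overlap and together cover at least 16 of the 17. Shuffled listings gave a median of 22 and a highest of 40 pairs (permutation p = 0.001, the smallest they can give). The shuffles treated all libraries as alike and each identifier as independent. They do not keep any tendency of certain libraries to lack the same identifiers, so this p does not single out the explanation. An example is MIR_831 and MIR_4572, listed by 2 and 15 of the full libraries with medians of 42652.5 and 49827 counts. Both values concern listing, so no biological explanation was tested.

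The third pattern is the difference of experiment 1 from the others on shared identifiers. Of 100 draws of 5 of the 17 libraries, only the real one gave as many as the 105 calls of a single-term model, the highest other giving 26. An arbitrary pick of 5 libraries thus did not reach this count in the other draws. The draws could take more than 1 library of a group, while those of experiment 1 all come from different groups. They were also chosen after experiment 1 had been seen to differ. For these reasons they do not exclude chance, and they do not measure the spread between experiments. With each library of experiment 1 left out, the single-term model gave 62 to 73 calls. A difference in library totals is argued against, since 86.9% of the 99 calls of the model with the groups were left with the total as a covariate, and the totals of experiment 1 (8006658 ± 954892, SD, n = 5) lay within the range of the others (7661005 ± 997342, SD, n = 12). The TMM-scaled totals nearly separated the experiments, at 5.34 to 5.86 (in units of 1e6) in experiment 1 against 5.60 to 8.74 in the others. With the TMM-scaled total as a covariate 43.4% were left, 0 identifiers were called for that covariate itself in edgeR, and the median size of the 99 in limma, in log2 units, went from 0.47 (median SE 0.11) to 0.46 (median SE 0.13), all 99 in the same direction. The share left lay between the bounds set beforehand, and the sizes were compared only after it was seen. Scaled depth as the whole cause is argued against, since it would have taken the sizes down to their error, and the lost calls ended with a larger error. A part played by depth is not excluded. Differences in the plants or handling of that experiment were not tested.

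For each of the 9 comparisons of 2 groups, all 10 splits of the 6 libraries gave as many calls as the real one (0, highest other 0), and 10 splits are too few for a share under 0.05. For each interaction, 30 of 30 splits gave at least the real 0 (highest other 0), which holds for any split and says nothing about chance, with 1022 and 1009 identifiers at an unadjusted p under 0.05 in edgeR and 1240 and 1168 calls in DESeq2. For any difference among the 7 groups, chance is not excluded, since 28 of 39 splits gave at least the real 130, the highest other giving 190. The DESeq2 calls at 2 h do not exclude chance either. On 2000 identifiers drawn at random, 7 of 36 regroupings within experiments gave at least the real 255 calls, the highest other giving 281. For all 24 h against all 2 h, 19 of 100 draws gave at least the real 1 call (highest other 8). With the block 12 of 100 draws within experiments gave at least the real 2 (highest other 4). Chance is not excluded for either count, though unlike the real groups after irrigation these draws could leave 1 library in a group. For all ammonium against water, 100 of 100 gave at least the real 0 (highest other 6), as any draw must, with 17 identifiers at an unadjusted p under 0.05 in edgeR and 0 calls in limma.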
